A study of Homo sapiens with 6 samples.

How the data were processed

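The data were 6 lists of RNA binding sites from PAR-CLIP in FlpIn T-REx HEK293 cells. FMR1 isoform 1 and isoform 7, each as wild type and as I304N, FXR1 and FXR2 had 1 library each, grouped by the immunoprecipitated protein given in the labels. Per the labels' protocols, transgenes were induced with 1 µg/ml doxycycline together with 100 µM 4-thiouridine for 16 h, cells were irradiated at 365 nm with 0.15 J per square cm, and lysates were treated with RNase T1 for 15 min at 22 °C before immunoprecipitation through the FLAG tag. The labels name a pair of Illumina sequencer models and do not say which library was run on which.

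Reads were aligned with Bowtie 0.12.7 to hg19, per the submitters' processing notes. The site caller, its thresholds, the reads per site and any pooling are not given in the sources used here. Each deposited line gives the chromosome, start, end, name, score and strand of a site. The deposited score is a flag and not a height: per the file headers it is 1000 for a site outside repeats and 0 for a site in a repeat. The deposited lists carry no read number, gene name or sequence, so every value here counts sites. Number of sites depends on sequencing depth and on the caller, and neither can be separated from binding here. A site seen by few reads weighs as much as a site seen by many.

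The annotation at hand was GENCODE release 29 on another build, GRCh38, and coordinates were not converted. Tested against it, 5.01% to 7.55% of sites per library fell on an exon of the same strand, against 2.32% to 3.20% after moving sites by 1 Mb, and it was not used. Gene names, transcript classes, the gene lists, the sequence motifs and the check of the labels through the transgenes had been planned and were not analysed here. In place of genes, strand-specific windows of 50 kb were used, a change made after the data had been seen.

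Shared sites were counted as sites overlapped by at least 1 nt on the same strand, for all 15 pairs of libraries. The chance level was the mean over 10 draws in which each site was moved by a random distance of 500 to 2000 nt in either direction. Without annotation, moved sites could not be kept within the same gene, transcript or exon. The moved share may therefore be lower than the share expected within the same transcript, and by an amount that may differ between libraries. Shares carry exact Clopper-Pearson intervals, ratios of shares exact conditional ones and differences of shares intervals by normal approximation, all at 95% and covering counting error only. The labels name no molecular identifiers, and the intervals say nothing of the spread between repeat experiments. The relative precision of a share is lowest in FXR1, with 9017 sites, where a count of 0 still allows 0.033% of sites (3 counts). Sites touching each other on a strand across libraries were joined into merged regions.

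For the window comparisons, site numbers were scaled to 100000 sites per library, a pseudocount of 1 was added, and windows with a mean of at least 2 sites over the libraries compared were kept. Log2 ratios were formed for I304N against wild type within each isoform, for isoform 7 against isoform 1 within each form, and for FXR1 and FXR2 against the mean of both wild-type FMR1 libraries. The numbers of windows with 2-fold changes come from these log2 ratios, which include the pseudocount. The ratios given for single windows are ratios of scaled counts without it. Where a count was 0, a bound was computed with 3 sites in its place. That bound leaves out counting error in the other library, so the exact conditional 95% limit is given beside it. No p-value was computed. An additive fit of form and isoform to the 4 FMR1 libraries would leave 1 residual degree of freedom, but it would take the isoforms as replicates, which the design fixed before the data did not do. Windows are not replicates either. Agreement of direction and the number of 2-fold changes without any difference were simulated 100 times by drawing Poisson site numbers from the pooled density of each window.

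The windows named in the text follow a rule fixed for genes before the data were examined. It takes the 5 densest windows per library, and the 10 windows up and 10 down ranked by the smaller of the 2 absolute log2 ratios for I304N and for the isoforms. For FXR1 and FXR2 it takes the 10 up and 10 down by log2 ratio. Mitochondrial windows were counted and not named, and the text gives a selection of the windows so ranked. Windows ranked by ratio were picked by the same counts that gave their ratios and intervals. Their ratios are therefore likely too extreme, and their intervals and limits do not allow for this choice.

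Alternatives tried were an overlap of at least 50% of the shorter site or of both sites, strand ignored, median-of-ratios scaling, pseudocounts of 0.5 and 5, no filter or a filter of 4 sites, the 5 densest windows left out, mitochondrial sites left out, and single wild-type isoforms as reference for FXR1 and FXR2. After the data had been seen, windows of 10 kb and 200 kb, thinning of every library at random to 9017 sites (20 draws for overlaps, 1 for windows), removal of repeat-marked sites, sites replaced by the 15 nt around their midpoint, removal of sites with identical ends, and removal of wild-type isoform 1 from the merged regions were added. The comparison of site ends and the removal of the densest 1% of windows for chromosome 19 were also added then.

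Overlap and window code was tested on simulated data. All planted overlaps were found (100%). The planted copies were moved by less than the width of the narrowest site, so this checks the code only. In a simulation of the I304N comparison over 8450 windows with 200 windows raised 4-fold, the mean recovered log2 ratio was 1.78 in isoform 1 and 1.79 in isoform 7, and 97.5% of the raised windows were at least 2-fold higher in both, against 0.86% of the others. The raised windows were drawn only from windows with site numbers well above the filter, so recovery in sparser windows was not tested. Computations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1.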

Results

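PAR-CLIP maps the RNA positions that a protein touches in living cells: a photoreactive nucleoside, here 4-thiouridine, is built into RNA, ultraviolet light at 365 nm links it to bound protein, and the RNA that comes down with the protein is sequenced. It was applied to FMR1, the fragile X protein, and to its paralogs FXR1 and FXR2. FMR1 was expressed as isoform 1 and as isoform 7, each in the wild-type form and with I304N, a single amino acid change in a KH domain, a fold that contacts RNA. The cells were HEK293, an established human embryonic kidney line, carrying tagged, doxycycline-inducible copies of each protein. Each of the 6 protein forms was represented by 1 library, so no value below has a replicate error. Intervals are 95% intervals, exact Clopper-Pearson for shares and exact conditional for ratios, and cover counting error only.

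The lists held 121903 sites for wild-type isoform 1, 78495 for wild-type isoform 7, 132219 for I304N isoform 1 and 88644 for I304N isoform 7. FXR2 had 34521 sites and FXR1 had 9017, the shortest list. Mean site width ran from 20.1 nt in FXR1 (SD 3.58 across sites) and 20.8 nt in FXR2 (SD 5.33) to 28.2 nt in I304N isoform 7 (SD 18.5) and 29.5 nt in wild-type isoform 1 (SD 24.99). Sites were crowded in wild-type isoform 1, where 12.9% (12.7 to 13.1) had no other site of the same library within 1000 nt on the same strand. That share was 15.6% in I304N isoform 1, 16.4% in I304N isoform 7, 28.9% in wild-type isoform 7, 29.5% in FXR2 and 46.5% in FXR1. Sites marked by the authors as lying in a repeat made up 3.03% of I304N isoform 1, 3.48% of I304N isoform 7, 3.91% of FXR2, 4.51% of wild-type isoform 7, 5.35% of wild-type isoform 1 and 6.11% (5.63 to 6.63) of FXR1.

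Some stretches of the genome were dense in several libraries. The window on chromosome 12 from 49400001 to 49450000 (hg19, minus strand) held 172 sites in wild-type isoform 1, 216 in wild-type isoform 7, 216 in I304N isoform 1 and 224 in I304N isoform 7, and ranked highest in the last 3 of these. It held 71 sites in FXR2 and 9 in FXR1. A window on chromosome 19 from 57800001 to 57850000 (plus strand) ranked highest in wild-type isoform 1, with 230 sites, and had 138 in I304N isoform 1 and 33 in FXR1. FXR1 was densest on chromosome 10 from 62550001 to 62600000 (plus strand), with 49 sites or 0.543% of its list (0.402 to 0.718). The same window held 208 sites in wild-type isoform 1 and 32 in wild-type isoform 7. FXR2 was densest on chromosome 21 from 34900001 to 34950000 (plus strand), with 110 sites, where the 4 FMR1 libraries had 93, 96, 76 and 68 sites in the order wild-type isoform 1, wild-type isoform 7, I304N isoform 1 and I304N isoform 7. Genes and transcript parts under these positions were not analysed here.

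The paralogs were compared with FMR1 to see how far the 3 proteins bind the same places. FXR1 and FXR2 sites fell most often on sites of wild-type isoform 1: 70.0% of FXR1 sites (69.0 to 70.9) and 64.4% of FXR2 sites (63.9 to 64.9) overlapped such a site by at least 1 nt on the same strand. Among FXR1 sites, 27.4% overlapped a site of I304N isoform 1, 21.2% a site of wild-type isoform 7 and 18.2% a site of I304N isoform 7. The corresponding shares of FXR2 sites were 46.2%, 32.1% and 34.8%. When FXR1 sites were moved at random by 500 to 2000 nt, 23.8% still met wild-type isoform 1, 11.6% I304N isoform 1, 7.71% wild-type isoform 7 and 8.41% I304N isoform 7. The moved shares of FXR2 sites were 18.6%, 11.7%, 7.52% and 8.94%. As a multiple of the moved share, FXR1 overlap was largest in wild-type isoform 1, 2.94 against 2.76 in wild-type isoform 7, 2.36 in I304N isoform 1 and 2.17 in I304N isoform 7. For FXR2 the multiple was smallest in wild-type isoform 1, 3.46 against 4.27, 3.96 and 3.89 in the same order, so the ranking of that library depended on the measure. With every library thinned to 9017 sites, FXR1 overlapped wild-type isoform 1 in 5.25% of sites (SD 0.270 over 20 draws) and the other FMR1 libraries in 1.91% to 2.44%. The corresponding values for FXR2 were 4.77% (SD 0.252) and 3.24% to 3.79%.

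**Figure D1:**
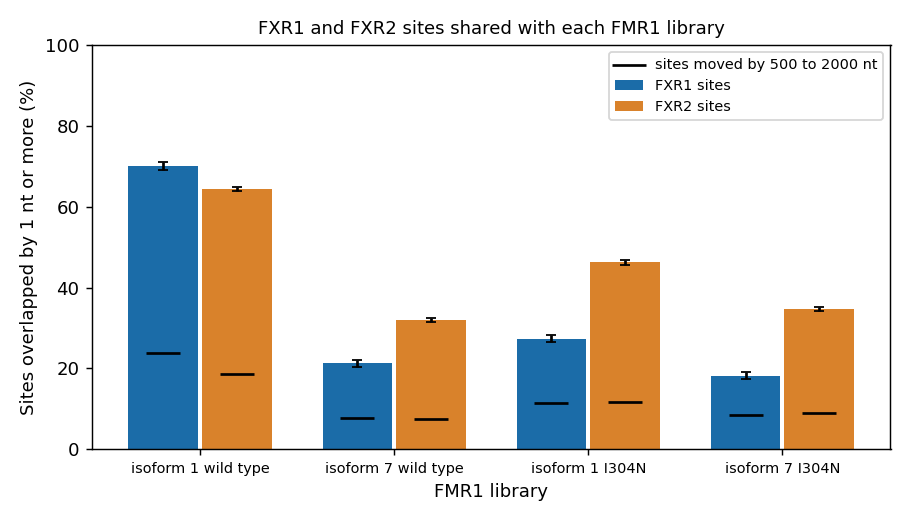
Bars show the percentage of FXR1 and of FXR2 sites overlapped by at least 1 nt in each FMR1 library, error bars the exact 95% counting interval, and black lines the percentage after the sites were moved by 500 to 2000 nt. The bars for wild-type isoform 1 stand at 70.0% and 64.4%, above those for the other 3 libraries, of which the highest is 46.2%.

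Sites of other libraries were also counted at longer range, where most shares were high and no chance level was computed. Within 1000 nt of an FXR1 site, wild-type isoform 1 had a site in 86.0% of cases (85.2 to 86.7), I304N isoform 1 in 79.1%, wild-type isoform 7 in 74.8% and I304N isoform 7 in 68.0%. For FXR2 sites these shares were 89.3%, 86.0%, 79.3% and 74.9%. FXR1 and FXR2 overlapped each other in 74.4% of FXR1 sites (73.5 to 75.3), against 6.44% after moving, and in 19.4% of FXR2 sites.

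Overlapping sites of some pairs of libraries had the same ends. FXR1 and FXR2 shared 3953 sites with both ends identical, 59.1% of their overlapping sites (58.0 to 60.3). In the other 14 pairs this share lay between 1.91% and 10.5%. Among sites of up to 22 nt, a limit chosen after seeing the data, the 5 prime end was the same in 83.3% of overlapping sites of FXR1 and FXR2, 65.1% of wild-type isoform 1 and FXR1 and 55.2% of wild-type isoform 1 and FXR2. It was the same in 39.7% (36.2 to 43.2) for wild-type isoform 7 and FXR1. I304N isoform 1 and I304N isoform 7 reached 35.8%, and wild-type isoform 7 reached 32.9% with I304N isoform 1 and 29.7% with I304N isoform 7. Wild-type isoform 1 lay lower with each other FMR1 library, at 27.7%, 27.3% and 26.3%. The labels name a pair of sequencer models without assigning libraries to them, so values within a sequencing batch could not be given.

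**Figure D2:**
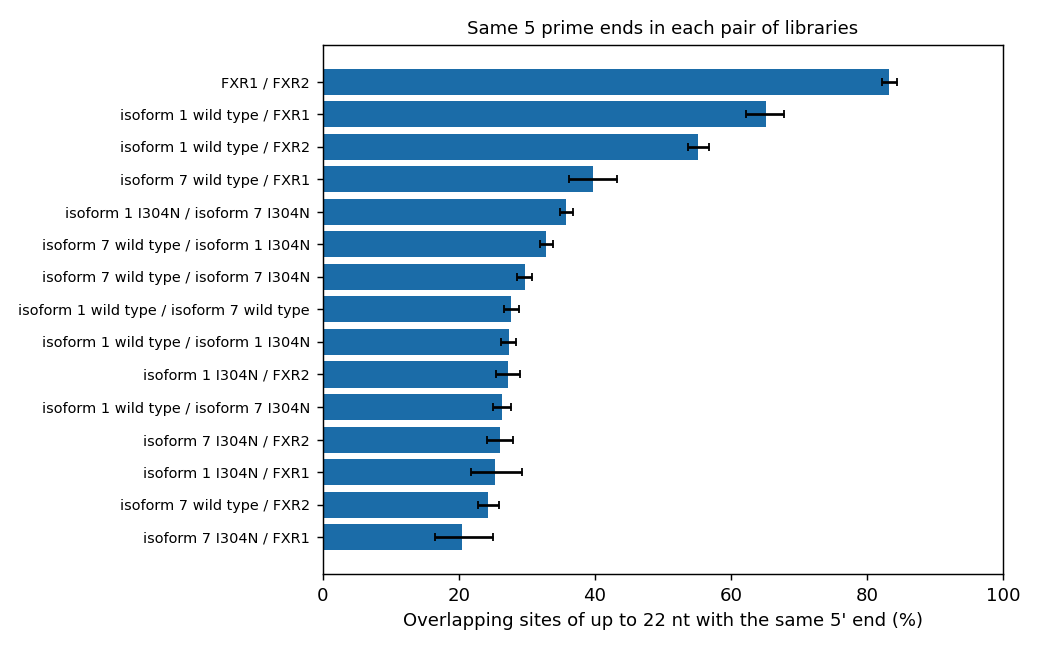
Bars show, for each of the 15 pairs of libraries, the percentage of overlapping sites of up to 22 nt that have the same 5 prime end, with exact 95% counting intervals. FXR1 with FXR2 stands highest at 83.3%, followed by wild-type isoform 1 with FXR1 at 65.1% and with FXR2 at 55.2%.

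Against the mean of both wild-type FMR1 libraries, the windows of 50 kb most raised in FXR1 and in FXR2 included several on chromosome 19, and those of FXR2 several on chromosome 17. On chromosome 19 from 21950001 to 22000000 (minus strand) FXR1 had 7 sites and FXR2 had 11, while each wild-type FMR1 library had 1. The scaled ratio to wild-type isoform 1 was 94.6 (12.2 to 4270) for FXR1 and 38.8 (5.65 to 1670) for FXR2, and that to wild-type isoform 7 was 60.9 (7.83 to 2750) and 25 (3.64 to 1080). Chromosome 19 held 4 of the 10 windows most raised in FXR1 and 3 of the 10 most raised in FXR2. In FXR2, 3 adjacent windows on chromosome 17 from 76400001 to 76550000 (minus strand) had 11, 14 and 10 sites, against 0, 0 and 1 in wild-type isoform 1. The middle window was at least 16.5-fold denser than wild-type isoform 1, counting 3 sites in place of 0, and the exact 95% limit, which also covers counting error in the other library, was 11.7. Such a limit follows each bound of this kind below. FXR1 had 42 sites on chromosome 12 from 1300001 to 1350000 (plus strand), 7.37 times the scaled density of wild-type isoform 1 (4.94 to 10.9) and 33.2 times that of wild-type isoform 7 (16.8 to 71.6). FXR1 had no site on chromosome 11 from 62250001 to 62300000 (minus strand), where wild-type isoform 1 had 168, so its density there was at least 4.14-fold lower (upper limit of the ratio 0.300). Against wild-type isoform 7, with 68 sites, it was at least 2.60-fold lower (upper limit 0.485). FXR2 had no site on chromosome 7 from 141150001 to 141200000 (plus strand), where wild-type isoform 1 had 43, at least 4.06-fold lower (upper limit 0.316), and wild-type isoform 7 had 18, at least 2.64-fold lower (upper limit 0.517).

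Over 5833 windows, FXR1 and FXR2 deviated from wild-type FMR1 in the same direction in 69.6% (68.4 to 70.7). Since both were compared with the same FMR1 libraries, 52.4% was obtained in 100 simulations without any difference. The covariance of the log2 ratios across windows was 1.24, against 0.152 in the simulations. Both simulated values hold counting error only. Variation of the shared FMR1 libraries beyond it would also move both ratios the same way, so these references may be too low. Windows are not independent replicates. At least 2-fold higher density in both was seen in 301 windows, against 97.5 if the lists were independent and 119.6 (SD 11.4) in the simulations. At least 2-fold lower density in both was seen in 1345, against 973.8 and 646.8 (SD 21.5). The first of these references leaves out the shared FMR1 libraries, and the second leaves out any real difference of either paralog from FMR1, so an excess over them is not a measure of a shared effect. Under median-of-ratios scaling these counts were 141 and 1999, and with each library thinned to 9017 sites they were 164 and 118 among the 1197 windows that then passed the filter. Thinning also changes the weight of the pseudocount and of single sites, and the cause of the reversed order was not tested. The median log2 ratio was -0.23 for FXR2 and -2.36 for FXR1. FXR1 had a site in 3806 windows and wild-type isoform 1 in 11524, and the FXR1 median depended on the settings: it was -3.22 and -0.919 with pseudocounts of 0.5 and 5, -1.20 with a filter of 4 sites and 0 after thinning. It is therefore not a measure of how dense FXR1 is in a typical window.

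The I304N libraries were set beside the wild-type libraries of the same isoform. Sites of I304N were more often on chromosome 19: 8.16% (8.02 to 8.31) in I304N isoform 1 against 4.91% (4.79 to 5.03) in wild-type isoform 1, and 10.1% (9.93 to 10.3) in I304N isoform 7 against 6.37% (6.20 to 6.54) in wild-type isoform 7. The ratio of shares was 1.66 (1.61 to 1.72) in isoform 1 and 1.59 (1.54 to 1.65) in isoform 7. Chromosomes 9, 17, 20 and 22 also held a larger share in I304N in both isoforms, so that 5 of 23 chromosomes were higher in both beyond their counting intervals. On 12 of 23 the share was lower in both, as on chromosome 4 (0.728 and 0.663 in isoforms 1 and 7) and chromosome 18 (0.694 and 0.678). The ratio for chromosome 16 was 1.63 (1.56 to 1.69) in isoform 1 and 0.959 (0.919 to 1.00) in isoform 7, and the difference between isoforms was not tested across replicates. Wild-type isoform 1 had 3.13% of its sites there. The share was 5.18% in wild-type isoform 7, 5.10% in I304N isoform 1 and 4.97% in I304N isoform 7.

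**Figure D3:**
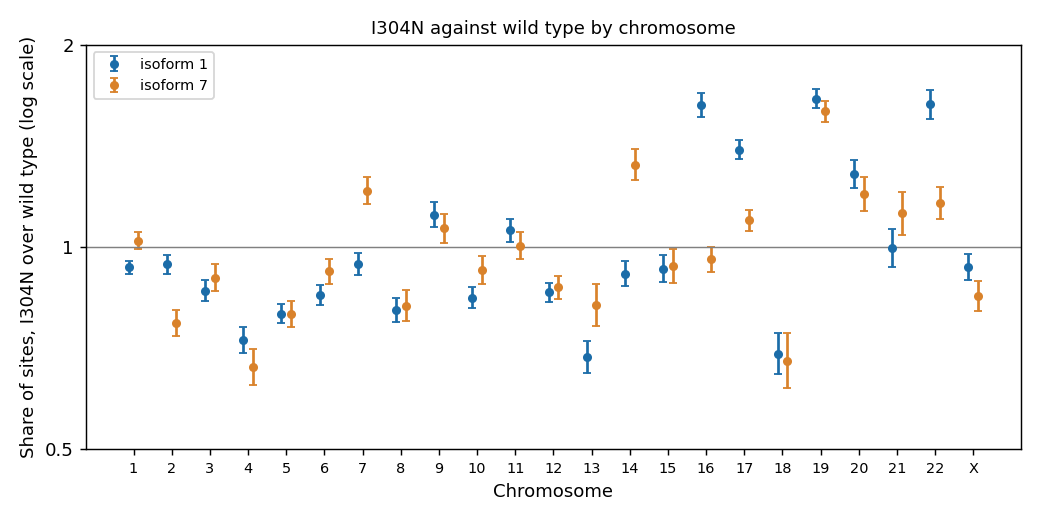
Points show, for each chromosome, the share of sites in the I304N library divided by the share in the wild-type library of the same isoform, on a log scale with exact 95% counting intervals. Chromosome 19 stands at 1.66 in isoform 1 and 1.59 in isoform 7, and chromosome 18 at 0.694 and 0.678.

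In windows of 50 kb, the strongest gains with I304N in both isoforms lay on several chromosomes. On chromosome 1 from 9650001 to 9700000 (plus strand) I304N isoform 1 had 36 sites and wild-type isoform 1 none, at least 11.1-fold higher (lower limit 8.54). There I304N isoform 7 had 50 sites and wild-type isoform 7 had 3, a scaled ratio of 14.8 (4.77 to 74.0). On chromosome 19 from 49250001 to 49300000 (minus strand) the counts were 24 against 1 in isoform 1, a ratio of 22.1 (3.61 to 910), and 30 against 0 in isoform 7, at least 8.86-fold higher (lower limit 6.77). A window on chromosome 14 from 24750001 to 24800000 (plus strand) had 18 against 0 sites in isoform 1 and 36 against 3 in isoform 7. The 10 windows with the strongest gains included 2 each on chromosomes 1, 12, 14 and 19.

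The 10 windows with the strongest losses in both isoforms lay on chromosomes 1, 3, 4, 7, 10, 12 and 17. On chromosome 12 from 1300001 to 1350000 (minus strand) I304N isoform 1 had 10 sites against 73 in wild type, a ratio of 0.126 (0.0581 to 0.246), and I304N isoform 7 had 0 against 13, at least 4.89-fold lower (upper limit 0.291). The opposite strand of this window was among the densest in FXR1 and FXR2. On chromosome 3 from 191100001 to 191150000 (plus strand) the ratio in isoform 1 was 0.0981 (0.0304 to 0.246), from 5 sites against 47. In isoform 7 that window had 0 against 7. On chromosome 4 from 123250001 to 123300000 (plus strand) the I304N libraries had no site, against 10 and 6 in wild-type isoforms 1 and 7.

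Of 8361 windows with a nonzero ratio in both isoforms, 5554 moved in the same direction with I304N, 66.4% (65.4 to 67.4), against 50.1% in simulations without a difference. Pearson's r of the log2 ratios was 0.41 and Spearman's rho was 0.43 across 8450 windows. At least 2-fold gains in both isoforms were seen in 1135 windows, against 583.6 for independent lists, and at least 2-fold losses in 631, against 335.2. With each library thinned to 9017 sites these counts were 112 and 95 among 1258 windows. In the full lists opposite changes of that size occurred in 429 windows, for which no reference was computed. Of 228477 merged regions with an FMR1 site, 19797 were found in both I304N libraries and neither wild-type library, and 4474 in both wild-type libraries and neither I304N library. With each FMR1 library thinned to 78495 sites these counts were 12475.6 (SD 28.5 over 5 draws) and 5362.2 (SD 38.3). Regions found only in wild-type isoform 7 and I304N isoform 1 then numbered 6928.0, and those only in wild-type isoform 1 and I304N isoform 7 numbered 3434.6. After this thinning, the pair without wild-type isoform 1 was the larger in every split into pairs. In the full lists that failed for the isoform split, with 1539 regions in both isoform 7 libraries only and 11954 in both isoform 1 libraries only. Wild-type isoform 7 lost no site in thinning. For the mixed pairs it held in the full lists too, at 7019 against 2088. Whether the I304N excess comes from I304N or from wild-type isoform 1 differing from the rest was not settled. Thinning also turns regions shared by more libraries into regions of a single pair. Without thinning, all 4 FMR1 libraries shared 21684 regions. Position by position, 44.6% (44.3 to 44.8) of wild-type isoform 1 sites overlapped an I304N isoform 1 site, and 49.8% (49.4 to 50.1) of wild-type isoform 7 sites overlapped an I304N isoform 7 site.

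Isoform 7 was compared with isoform 1 within the wild type and within I304N. Chromosomes 19, 21 and 22 held a larger share of its sites in both forms, beyond the counting intervals. Of 23 chromosomes, 8 were lower in both (2, 3, 4, 5, 8, 10, 12 and 18), and chromosome 14 went in opposite directions. A window on chromosome 16 from 88800001 to 88850000 (minus strand) had 11 sites in wild-type isoform 7 and 1 in wild-type isoform 1, a scaled ratio of 17.1 (2.48 to 735). With I304N it had 99 sites in isoform 7 and 11 in isoform 1, a ratio of 13.4 (7.19 to 27.8). On chromosome 19 from 40750001 to 40800000 (minus strand) the ratios were 13.6 (4.86 to 52.6) and 3.85 (2.37 to 6.46). On chromosome 21 from 45200001 to 45250000 (plus strand), wild-type isoform 7 had 11 sites against 0, at least 5.69-fold higher (lower limit 3.90), and I304N isoform 7 had 89 against 23. Isoform 7 was sparse on chromosome 1 from 211700001 to 211750000 (minus strand), with 2 sites against 62 in the wild type, a ratio of 0.0501 (0.00594 to 0.189), and 0 against 18 with I304N, at least 4.02-fold lower (upper limit 0.339).

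Over all windows, agreement was lower for the isoforms than for I304N against wild type. The direction was the same in the wild type and with I304N in 4923 of 8256 windows, 59.6% (58.6 to 60.7), against 49.9% in simulations, with a Pearson's r of 0.14 and a Spearman's rho of 0.20 across windows. Isoform 7 was at least 2-fold higher in both forms in 154 windows, against 94.4 for independent lists, and at least 2-fold lower in 463, against 345.0. With each library thinned to 9017 sites these counts were 79 and 57 among 1258 windows. Without thinning, opposite changes of at least 2-fold occurred in 393 windows, beside 154 shared gains and 463 shared losses. No reference for independent lists was computed for opposite changes, so this number is no sign of disagreement. Regions in both isoform 1 libraries and neither isoform 7 library numbered 11954, and 1539 regions had the reverse pattern. After thinning to 78495 sites the counts were 5061.8 (SD 114.7) and 8188.6 (SD 20.3), in the reverse order. Wild-type isoform 7 lost no site in this thinning. Removing sites of isoform 1 can leave regions shared by more libraries in the isoform 7 pair only. The reversed order is therefore no measure of a difference between the isoforms. Among wild-type isoform 7 sites, 48.5% (48.2 to 48.9) overlapped wild-type isoform 1 and 66.4% (66.0 to 66.7) overlapped I304N isoform 1. Among I304N isoform 7 sites, 75.9% (75.6 to 76.2) overlapped I304N isoform 1.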

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

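The comparisons of site ends and the test within isoform 7 were chosen after the results had been seen. The other tests in the next 3 paragraphs were fixed before their own results, though after the data had been seen. The one without repeat-marked sites was set aside and taken up again once its result was known.

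FXR1 and FXR2 sites coincided with sites of wild-type isoform 1 more often than with sites of the other FMR1 libraries, although relative to moved sites FXR2 had its lowest multiple there, 3.46 against 3.89 to 4.27. List length does not account for it, since with 9017 sites per library the FXR1 share in wild-type isoform 1 exceeded the next by 2.81 points (SD 0.37 over draws). Broader sites in that library do not either, since with 15 nt per site the gap was 35.1 points. A library preparation or sequencing run shared by wild-type isoform 1, FXR1 and FXR2 is a candidate explanation: the lowest of their 3 pairs had the same 5 prime end in 55.2% of overlapping sites of up to 22 nt, above the highest of the 9 pairs with the other libraries, 39.7% for FXR1 with wild-type isoform 7. A closer likeness of FXR1 and FXR2 to wild-type isoform 1 in binding remains open beside it, because no reads or batch labels were used here.

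Wild-type isoform 7 sites coincided with I304N isoform 1 more often than with wild-type isoform 1. After thinning, the gap was still 0.922 points (SD 0.3 over draws), which argues against list length as the whole cause. Wild-type isoform 7 then met I304N isoform 7 in 5.27% of sites (SD 0.268), I304N isoform 1 in 4.62% and wild-type isoform 1 in 3.70%. In these thinned shares wild-type isoform 1 was lowest, and I304N isoform 1 was not highest. In the full lists I304N isoform 1 was highest, at 66.4% against 49.8% for I304N isoform 7 and 48.5% for wild-type isoform 1. As multiples of the moved share these were 6.215, 6.052 and 3.951. Thinning removed a larger part of the longer I304N isoform 1 list. The gap thus goes with a low overlap of wild-type isoform 1 in thinned shares and multiples. A tie particular to wild-type isoform 7 and I304N isoform 1 was not excluded. Whether these 2 libraries shared a preparation cannot be told: 32.9% of their narrow overlapping sites had the same 5 prime end, more than the 27.7% of wild-type isoform 7 with wild-type isoform 1 but less than the 39.7% of wild-type isoform 7 with FXR1. An exchange of labels between wild-type isoform 7 and I304N isoform 1 was not tested and remains open. It would leave the overlap of these 2 lists with each other unchanged.

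Chromosome 19 held a larger share of sites in I304N than in wild type in both isoforms. A preparation particular to wild-type isoform 1 is not the whole cause, because the rise within isoform 7, which does not involve that library, was 3.76 points, with an interval of 3.50 to 4.02. A few dense windows and repeat-marked sites are not the cause in isoform 1, where the rise was 3.55 points without the densest 1% of windows and 3.40 points without sites marked as repeat. Differences between the stable lines in which RNAs were expressed, or between single library preparations or runs, were not tested. They remain open beside an effect of the amino acid change. Relative to wild-type isoform 1, the chromosome 19 share was also higher in libraries without I304N. The ratio was 1.30 in wild-type isoform 7, 1.20 in FXR1 and 1.30 in FXR2, each below the 1.66 of I304N isoform 1. The I304N ratio of 1.59 in isoform 7 has another reference, wild-type isoform 7.

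Some differences between I304N and wild type went in opposite directions in the isoforms, and none of them was tested. Mean site width differed by -1.48 nt in isoform 1 and by 4.98 nt in isoform 7. It was 28.0 and 28.2 nt in I304N isoforms 1 and 7, and 29.5 and 23.2 nt in the wild-type ones. The share of sites with no other site within 1000 nt differed by 2.66 points in isoform 1 and by -12.42 points in isoform 7. It was 15.6% and 16.4% in I304N isoforms 1 and 7, and 12.9% and 28.9% in the wild-type ones. For width and for this share, the opposite signs thus go with a difference between the wild-type libraries. The share of sites on chromosome 7 had a ratio of I304N to wild type of 0.944 in isoform 1 and 1.21 in isoform 7. On chromosome 14 the ratios were 0.913 and 1.33. On chromosomes 7 and 14 the shares differed more between the I304N libraries than between the wild-type ones.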

How the results depend on the processing

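Thinning to 9017 sites, repeat removal, 15-nt sites and 10-kb and 200-kb windows were chosen after seeing the data. So were the removal of identical sites, of wild-type isoform 1 and of the densest 1% of windows. Of 102 recomputed main values, 55 stayed within the counting interval or 1.5 times the main count, and 47 did not. Some of the 55 could not have moved. A pseudocount does not change the sign of a log2 ratio. Site totals without mitochondrial or repeat-marked sites were bound to stay within 1.5 times, because such sites are few. The 55 are therefore not a measure of robustness. Wild-type isoform 1 ranked highest for FXR1 and for FXR2 under 7 of 7 overlap alternatives, and wild-type isoform 7 met I304N isoform 1 more often than wild-type isoform 1 under 7 of 7. The shares in the next paragraph fell with stricter rules or fewer sites; the cause of the shifts under repeat removal and between window settings was not tested.

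Shares are listed here as wild-type isoform 1 in I304N isoform 1, wild-type isoform 7 in I304N isoform 7, wild-type isoform 7 in wild-type isoform 1, I304N isoform 7 in I304N isoform 1, FXR1 in wild-type isoform 1 and FXR2 in wild-type isoform 1. With 50% of the shorter site required they were 42.5%, 48.4%, 46.2%, 74.6%, 68.7% and 62.7%. With 50% of both sites they were 28.5%, 36.5%, 29.4%, 61.8%, 37.6% and 36.5%. After thinning they were 3.21%, 5.27%, 3.70%, 5.36%, 5.25% and 4.77%. With 15 nt per site they were 35.8%, 43.1%, 38.1%, 67.8%, 51.2% and 49.5%. Without repeat-marked sites they were 45.0%, 50.3%, 48.0%, 68.0% and 63.1%, I304N isoform 7 in I304N isoform 1 staying within its interval. FXR1 in FXR2 was 72.6% with 50% of both sites, 19.2% after thinning, 75.6% without repeats and 54.4% without identical sites.

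The share of windows with the same direction, for I304N, isoform and FXR comparisons in turn, was 62.3%, 55.3% and 80.8% without a filter and 60.0%, 55.1% and 71.6% after thinning. For I304N and isoform it was 67.7% and 61.7% with a filter of 4 sites and 65.0% and 57.8% in 200-kb windows. For the FXR comparison it was 77.0% with median-of-ratios scaling, 64.7% against wild-type isoform 1 alone and 72.9% against wild-type isoform 7 alone. That scaling moved the median log2 ratio of I304N in isoform 1 from 0.27 to 0.03 and that of FXR2 from -0.23 to -0.66. Over the alternatives other than thinning, 2-fold gains and losses in both contrasts ranged from 402 to 1539 and 160 to 842 windows for I304N, 24 to 337 and 48 to 674 for isoform 7, and 141 to 738 and 705 to 4848 for FXR1 and FXR2. After thinning they were 112 and 95, 79 and 57, and 164 and 118. Regions in both I304N libraries only numbered 12476 after thinning and 29310 without wild-type isoform 1. Leaving out that library drops a condition for absence, so the second count could hardly fall and is no test of the excess.

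Alternatives that need a value per site, annotation or sequence were not run, nor were sites called in both libraries, which would fix the outcome. Reads per site were not given, so what depth limits cannot be told; relative counting error is largest for the short FXR1 list. The within-isoform pairs of FMR1 were not fitted together, because the isoforms were not taken as replicates.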

Other observations

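The mitochondrial genome showed strand patterns that differed between libraries. FXR1 had 18 sites there and FXR2 had 35, all of them on the plus strand, which carries most mitochondrial genes, with lower interval bounds of 81.5% and 90.0%. In wild-type isoform 1 the plus strand held 125 of 146 sites, 85.6% (78.9 to 90.9). It held 143 of 242 in wild-type isoform 7 (59.1%, 52.6 to 65.3), 31 of 72 in I304N isoform 1 (43.1%, 31.4 to 55.3) and 31 of 86 in I304N isoform 7 (36.05%, 26.0 to 47.1). Wild-type isoform 7 had the largest mitochondrial share among the FMR1 libraries, 0.308% of sites, and I304N isoform 1 the smallest, 0.054%.

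Among regions found in exactly 2 FMR1 libraries, those with a site in wild-type isoform 1 held an FXR1 site more often. An FXR1 site lay in 4.89% (4.28 to 5.57) of regions found in both wild-type libraries only, 3.60% of those in both isoform 1 libraries only and 3.35% (2.62 to 4.22) of those in wild-type isoform 1 and I304N isoform 7 only. Without wild-type isoform 1 it was 0.541% (0.383 to 0.742) for wild-type isoform 7 with I304N isoform 1, 0.192% (0.136 to 0.263) for both I304N libraries and 1 of 1539 for both isoform 7 libraries. In the same order, FXR2 sites lay in 12.5%, 12.5% and 10.1% of the first 3 kinds of region and in 4.17%, 4.17% and 2.14% of the others. Regions found in all 4 FMR1 libraries had an FXR1 site in 7.13% and an FXR2 site in 34.2%. Repeat-marked sites lay in 9.01% of the regions found in both wild-type libraries only and in 3.05% of those found in both I304N libraries only.

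FXR1 sites that overlapped an FXR2 site differed from the rest of the FXR1 list. Of these 6706 sites, 82.1% (81.1 to 83.0) overlapped wild-type isoform 1, against 34.9% (33.0 to 36.9) of the other 2311. Overlap with I304N isoform 1 was 32.7% and 11.8%, and overlap with I304N isoform 7 was 22.3% and 6.58%. Overlap with wild-type isoform 7 changed less, from 22.5% to 17.6% (16.0 to 19.2), and 201 FXR1 sites had both ends identical with a wild-type isoform 7 site.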
